A study of Tabanus nipponicus with 3 samples.

How the data were processed

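RNA was sequenced from the midguts of 3 wild-caught adult female horse flies of the species Tabanus nipponicus, a blood-feeding fly of the family Tabanidae. Per the labels' protocols, each midgut was dissected under sterile conditions and kept as a sample of its own, RNA was extracted with TRIzol, and libraries were made from total RNA with a KAPA RNA HyperPrep kit. The labels give 1 group, female midgut, with replicates 1 to 3, called fly 1, fly 2 and fly 3 here. The column of fly 3 carries the number 4 in the deposited table and was matched through the description of the third replicate in the labels. The feeding state and age of the flies are not given in the sources used here.

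The deposited table gives an FPKM value, a read number scaled to transcript length and sequencing depth, for each of 8039 unigenes in each fly, per the file headers. A unigene is a transcript assembled from the reads without a genome, and the identifiers carry the prefix of the assembler Trinity. The versions of the assembler, the filters on assembled transcripts, the read aligner and the counting tool are not given in the sources used here. The deposited table also lists the length of each unigene, its best protein hit and the percent of identical residues in that alignment, per the file headers. The protein database and search tool are not named there. A best hit was listed for 7898 unigenes and no hit for 141, and the median identity was 65.5%. The best hit came from the black soldier fly Hermetia illucens for 4240 unigenes and from the genus Tabanus for 13, so names are those of the nearest listed protein in another species. No reference genome was used here, so no chromosome position is given, and unigene lengths ran from 316 to 23873 bases. Reads shared between similar transcripts, such as members of the protease families, can be divided between unigenes in ways the table does not show.

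FPKM multiplied by length summed to 1e+09 in each fly, so the values were scaled to the unigenes in the table alone. Dividing that product by its smallest value above 0 in a fly gave whole numbers, within 0.001, for 97.1%, 97.3% and 97.3% of unigenes in flies 1, 2 and 3. The remaining values were multiples of 0.01, as when shared reads are counted in fractions. The recovered depths were 31922570, 33797869 and 29308867 reads in flies 1, 2 and 3. Even numbers made up 79.3%, 79.3% and 79.0% of the recovered values, so mates of a pair appear to have been counted singly, and the counting error was computed for fragments of 2 mates. For the 5256 unigenes with a mean FPKM of at least 5, the median counting error was 4.22% and the median coefficient of variation between flies was 26.6%. The squared differences between flies had a median of 8.51 to 30.6 times the counting variance. Without any difference the value would be 0.455, so no library appeared to be listed 2 times. This cannot tell separate flies from repeat libraries of 1 fly, and the 3 libraries were counted as separate samples by the labels. Floors for values of 0 were set at 3 fragments, or 6 reads, per fly, and floors cover counting error only.

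Values were analysed as log2(FPKM + 1), a scale that understates differences of low unigenes. FPKM values are not counts, and no count model was used. A unigene counted as detected at an FPKM of at least 1. Names of best hits were searched with 45 lists of word patterns, fixed before the data were examined, for digestive enzymes, transporters, blood meal handling, detoxification, immunity, housekeeping functions, other cell types and other organisms. A unigene could belong to more than 1 list. For each list the share of summed FPKM was taken per fly. The level of a list was its median log2 value over flies, given as a percentile among 10000 random lists of unigenes with a hit. The variability of a list was the median between-fly SD of its members with a mean FPKM of at least 1, and its shift in a fly was the median difference between that fly and the mean of the other 2. Both were given as percentiles among 10000 random lists matched on mean expression in 20 bins. Lists with fewer than 5 members got no percentile. Percentiles of at least 97.5 or at most 2.5 are called outside the random lists. They describe these libraries and carry no p-value, since genes are not replicates. Ratios of summed FPKM between 2 lists were tested within flies by an exact sign-flip permutation test, two-sided, whose smallest p with 3 flies is 0.25. A unigene was called variable when its mean FPKM was at least 5 and its highest and lowest fly differed at least 4-fold in FPKM + 1.

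Named unigenes are the 25 with the highest mean FPKM, the 3 members of each list with the highest mean FPKM, and the 20 with the largest SD of log2 values among those with a mean FPKM of at least 5. Those without a protein hit were mostly left out of the text. A few others are named where stated as chosen after their values were seen. The plans assumed that hits from 2 protein databases would be listed, but the table gives 1 best hit, so the alternative that takes the other database first was not run. Some word patterns matched proteins of another kind. Alternatives chosen after seeing the data were lists without such matches, lists without unigenes whose best hit is in Bacteroides fragilis or Phocaeicola vulgatus, list variability and shifts with no filter on low values, names from the first title only, and shares of reads. The other alternatives were pseudocounts of 0.1 and 0.01, filters on low values, detection at an FPKM of 0.1 or 5, rescaling to a common sum, median-of-ratios scaling, leaving out the 10 most abundant unigenes, and leaving out each fly in turn. List percentiles were tested on simulated reads of 8039 unigenes. Lists changed 2-fold or 4-fold in fly 3 were called in 2 of 2 cases for each size, in either direction, and 1 of 40 unchanged lists was called. The unchanged lists were drawn at random from unigenes simulated independently. The check therefore does not show how often lists whose members vary together are called. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.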

Results

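The transcriptome of the midgut, the part of the gut where a meal is digested and absorbed, was measured by RNA sequencing in 3 individual female horse flies of the species Tabanus nipponicus. All 3 libraries belonged to 1 group, with 1 library per fly and 29308867 to 33797869 recovered reads, so the values describe levels and the spread between individuals and compare no treatments. Of the 8039 unigenes, 6948 reached an FPKM of 1 in fly 1, 6898 in fly 2 and 7637 in fly 3, with a mean of 7161 ± 413 (SD, n = 3), and 6560 did so in all 3 flies. Fly 3 alone reached that level for 528 unigenes, fly 1 alone for 73 and fly 2 alone for 30. These counts were not repeated with median-of-ratios scaling, which divides the values by 0.976, 0.838 and 1.27 in flies 1, 2 and 3. Pearson's r of log2(FPKM + 1) across unigenes, which are not independent replicates, was 0.94 between flies 1 and 2, 0.89 between flies 1 and 3 and 0.91 between flies 2 and 3, with Spearman's rho of 0.925, 0.871 and 0.884.

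A few unigenes took much of the midgut transcriptome. The most abundant unigene was named serine protease (TRINITY_DN1526_c0_g1_i1, 1508 bases), from the enzyme family that cuts dietary proteins, at 95287 ± 60558 FPKM (SD, n = 3). It held 15.7% of all FPKM in fly 1, 24.2% in fly 2 and 5.15% in fly 3. A second unigene of this name (TRINITY_DN24531_c0_g2_i4) stood at 31676, 42409 and 7636 FPKM in flies 1 to 3. The best hits of both came from the bacterium Bacteroides fragilis, with 88.6% and 84.2% identity. An uncharacterized protein (TRINITY_DN3949_c0_g1_i4) ranked between them, at 30687, 9209 and 50919 FPKM, and 2 more (TRINITY_DN262_c0_g1_i6 and TRINITY_DN4668_c0_g1_i2) likewise had their lowest value in fly 2 and their highest in fly 3. The 10 most abundant unigenes held 32.1% ± 6.93 of all FPKM and the 100 most abundant held 63.3% ± 6.65 (SD, n = 3).

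**Figure D1:**
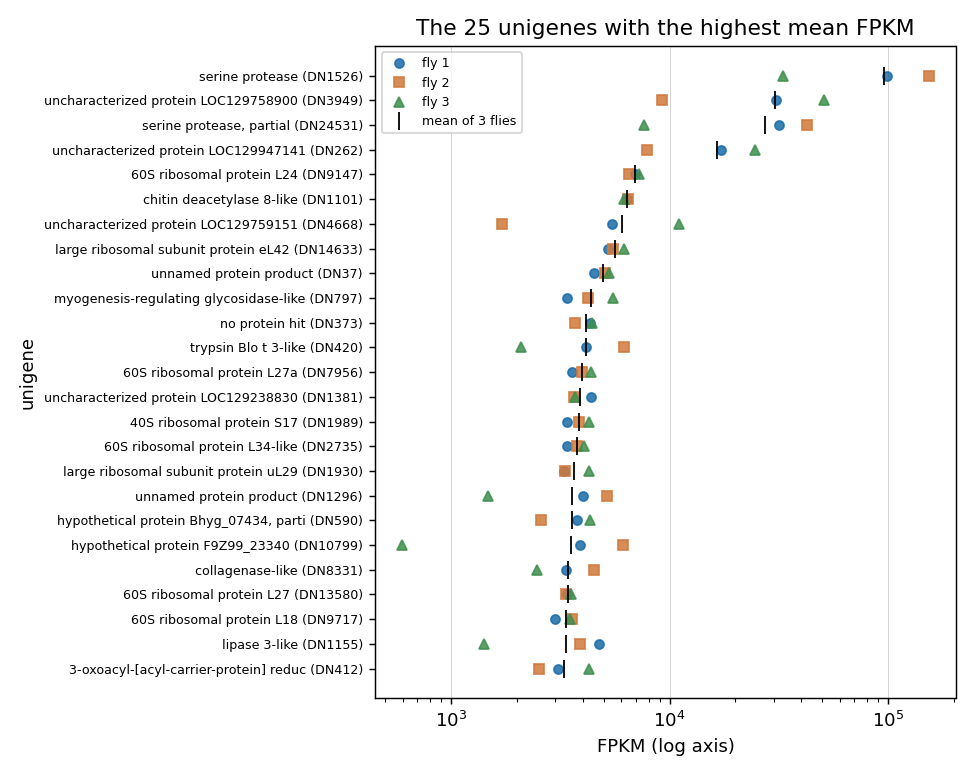
FPKM on a log axis of the 25 unigenes with the highest mean, 1 symbol per fly and a vertical tick at the mean of 3 flies. The most abundant serine protease lies at 33028 FPKM in fly 3 and at 153987 in fly 2, while chitin deacetylase 8-like lies at 6347 ± 136 (SD, n = 3).

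Other abundant unigenes differed between flies to unequal degrees. A hypothetical protein (TRINITY_DN10799_c0_g1_i4), also with a best hit in Bacteroides fragilis, was at 3874, 6140 and 594 FPKM in flies 1 to 3. Lipase 3-like (TRINITY_DN1155_c0_g3_i7) was at 4744, 3882 and 1415 FPKM. Chitin deacetylase 8-like (TRINITY_DN1101_c0_g1_i4), named for enzymes that modify chitin, was at 6347 ± 136 FPKM and ribosomal protein L24 (TRINITY_DN9147_c0_g1_i1) at 6916 ± 358 (SD, n = 3). The 58 unigenes matched as cytosolic ribosomal proteins, which build the ribosome, held 17.8% ± 1.13 of all FPKM. As a share of reads, which weights unigenes by length, they held 10.4%. Without members whose best hit is in Bacteroides fragilis or Phocaeicola vulgatus, the share of FPKM was 17.7%. The median between-fly SD of the 58 unigenes, 0.13 on the log2 scale, lay at percentile 0 of the matched random lists. After median-of-ratios scaling it was 0.25, at percentile 0.02. The 15 subunits of the V-type ATPase, a proton pump of gut cells, held 0.632% ± 0.0594, and their median SD of 0.13 lay at percentile 0.01, a place that depended on the scaling, since it was 58.4 after median-of-ratios scaling. The 42 translation factors held 1.04% ± 0.0268 and the 41 unigenes of oxidative phosphorylation 1.52% ± 0.382 (SD, n = 3), or 0.997% of reads.

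Protein digestion was the largest digestive function by expression. The 232 unigenes of all digestive lists held 26.7%, 36.4% and 10.8% of all FPKM in flies 1, 2 and 3, and the 107 serine proteases alone held 23.7%, 33.8% and 8.36%, a mean of 22.0% ± 12.8 (SD, n = 3). Of these, 7 had a best hit in the bacteria Bacteroides fragilis or Phocaeicola vulgatus and held 21.7%, 31.6% and 6.90%, and the 100 others held 1.98%, 2.20% and 1.46%. The 13 trypsins held 1.03% ± 0.316, led by trypsin Blo t 3-like (TRINITY_DN420_c0_g1_i4) at 4136 ± 2035 FPKM and trypsin-1-like (TRINITY_DN2354_c0_g1_i1) at 1397 ± 686, and their median level lay at percentile 99.98 of the random lists. The 13 unigenes matched as chymotrypsins held 0.034% ± 0.0322 (SD, n = 3), with a level at percentile 1.07, and 0.0157% without fly 3. Without 4 false name matches the other 9 held 0.032% ± 0.0291 (SD, n = 3). Collagenase-like (TRINITY_DN8331_c0_g1_i3) was at 3436 ± 1015 FPKM. Most members of the other serine protease list were low, and their median level lay at percentile 0. Without the 10 most abundant unigenes the share of serine proteases was 3.97% and that of all digestive lists 7.93%, while trypsins held 1.55%, carboxypeptidases 0.525%, aminopeptidases and dipeptidases 0.321%, lipases 0.836% and amino acid transporters 0.317%.

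Peptides are trimmed from their ends by exopeptidases. Carboxypeptidases, which act at one end, held 0.342% ± 0.191, with carboxypeptidase B-like (TRINITY_DN818_c0_g1_i9) at 1910 ± 1164 FPKM, and aminopeptidases and dipeptidases held 0.214% ± 0.0490 (SD, n = 3). As shares of reads these were 0.936% and 0.432%. Cathepsins and aspartic proteases, enzymes of lysosomes and of some insect guts, held 0.218% ± 0.123, and cathepsin L (TRINITY_DN3608_c0_g1_i32) was at 285, 167 and 1145 FPKM in flies 1 to 3. Amylases and glucosidases, which digest starch and sugars, held 0.725% ± 0.0605, led by maltase A3 (TRINITY_DN5820_c0_g1_i5) at 2152 ± 574 FPKM. The word patterns did not match myogenesis-regulating glycosidase-like (TRINITY_DN797_c0_g1_i2), at 4367 ± 1054 FPKM, so it is not in this share. Unigenes matched as lipases, enzymes that split fats and other lipids, held 0.550% ± 0.272. Lipase 3-like (TRINITY_DN1155_c0_g3_i7) at 3347 ± 1728 FPKM was their most abundant member. Next came phosphatidylserine lipase ABHD16A (TRINITY_DN6952_c1_g1_i2) at 89.6 ± 10.6 and (Lyso)-N-acylphosphatidylethanolamine lipase (TRINITY_DN21238_c0_g1_i8) at 22.5 ± 12.7 FPKM. Both are named for phospholipids, so not all members need digest dietary fat. Of reads, amylases and glucosidases held 1.16% and lipases 0.953%. Unigenes of the peritrophic matrix, the chitin and protein sheet that surrounds a meal, and of mucins held 0.530% ± 0.143, among them chitinase-3-like protein 1 (TRINITY_DN1345_c0_g1_i18) at 1465 ± 474 FPKM and a chitin synthase (TRINITY_DN1165_c0_g1_i15) at 448 ± 78.1 (SD, n = 3).

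**Figure D2:**
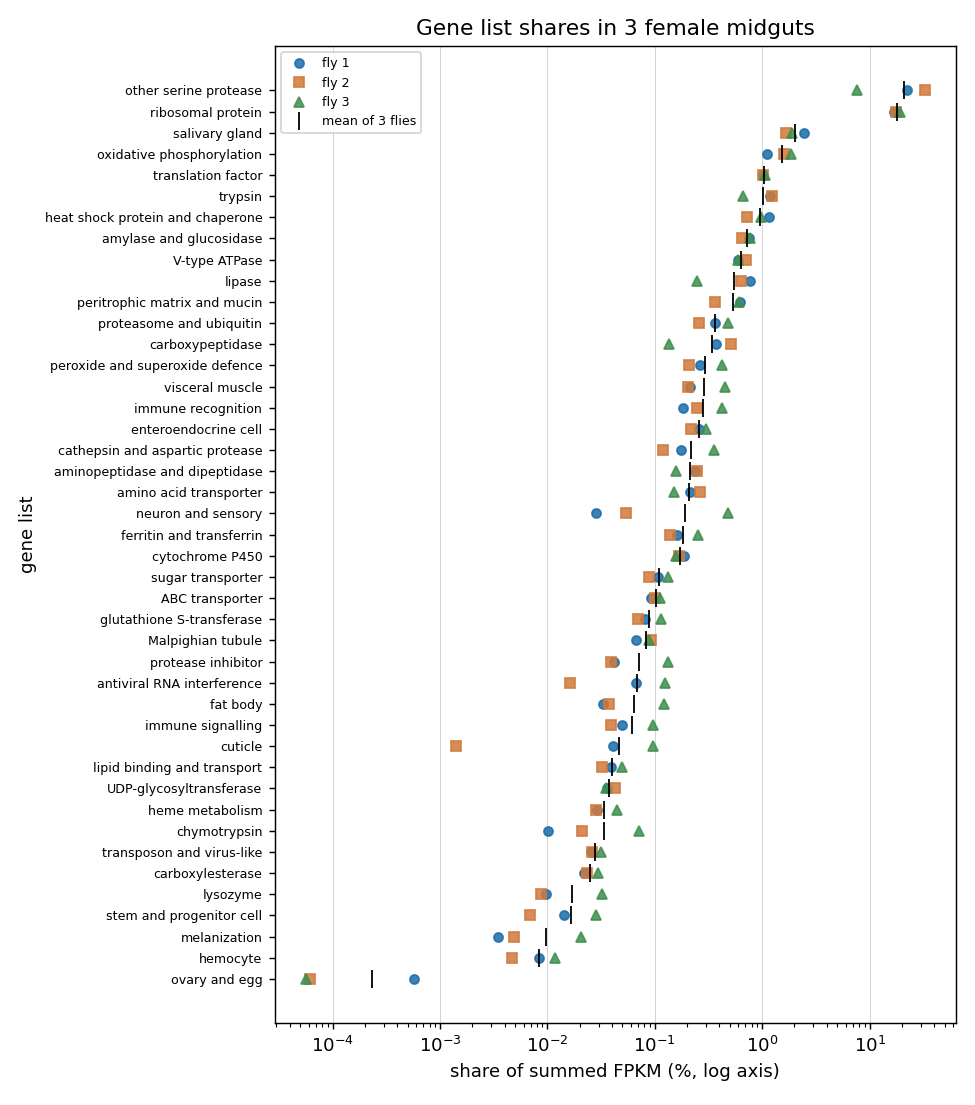
Share of summed FPKM in percent, on a log axis, of each gene list with members, 1 symbol per fly and a vertical tick at the mean of 3 flies. The other serine protease list lies at 22.5%, 32.6% and 7.62% in flies 1, 2 and 3, and ribosomal proteins lie between 16.8% and 19.0%.

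Ratios between lists within a fly were compared for 7 planned pairs. Summed trypsin exceeded chymotrypsin 115-fold, 58.7-fold and 9.43-fold in flies 1, 2 and 3. This ratio leaves out the other serine protease list, named as neither, which held 20.9% ± 12.5 of all FPKM (SD, n = 3). Serine proteases together exceeded exopeptidases 38.8-fold, 44.5-fold and 28.5-fold. Digestive lists exceeded immune lists 87.8-fold, 118-fold and 16.4-fold. Membership was set by name, so the digestive lists include protease inhibitors and may include serine proteases of the immune cascade. Without the unigenes with a best hit in Bacteroides fragilis or Phocaeicola vulgatus, the excess was 3.24-fold, 2.90-fold and 4.96-fold for serine proteases and 16.3-fold, 15.5-fold and 5.90-fold for digestive lists. Cytochrome P450 enzymes, which oxidise foreign compounds, exceeded glutathione S-transferases, which couple them to glutathione, 2.31-fold, 2.44-fold and 1.39-fold. Ferritins and transferrins, which bind iron, were lower than enzymes against peroxide and superoxide in all 3 flies, with a mean log2 ratio of -0.67 ± 0.07 (SD, n = 3). This depended mostly on a hypothetical protein (TRINITY_DN17066_c0_g1_i8) at 696 ± 299 FPKM that only a later title of its best hit calls thioredoxin, since with first titles alone the ratios were 0.968, 1.02 and 0.987 (exact permutation p = 0.75). With all titles and members, each of these 5 ratios had the same direction in 3 of 3 flies and an exact sign-flip permutation p of 0.25, the smallest that 3 flies allow, so none could reach a conventional threshold. Adjustment over the family cannot lower that value. Amylases and glucosidases stood at 0.973, 1.04 and 3.12 times lipases, with an exact permutation p of 0.5. The pair of lysozymes and antimicrobial peptides gave no ratio, because no unigene matched the antimicrobial peptide list. Filters on assembled transcripts or naming could leave such peptides out of the table, so their absence from the gut is not shown. The immune lists in the ratio to digestive lists hold none of them. With the median member in place of the sum, 4 of the ratios changed direction, those of serine proteases (log2 ratio -1.54), digestive lists (-0.045), cytochrome P450 enzymes (-2.24) and ferritins and transferrins (1.42). Without the most abundant member of each list, the mean log2 ratio of amylases and glucosidases to lipases was 4.19 against 0.55, that of digestive to immune lists 4.72 against 5.79 and that of trypsin to chymotrypsin 4.70 against 5.32. With the median member, those of amylases and glucosidases and of trypsin were 2.39 and 4.34.

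Uptake, iron and defence functions were expressed in all 3 flies. Amino acid transporters held 0.210% ± 0.0580 of all FPKM and sugar transporters 0.110% ± 0.0225, with the trehalose transporter Tret1 (TRINITY_DN403_c0_g1_i8) at 497 ± 154 FPKM. Of reads they held 0.342% and 0.171%. A ferritin unigene (TRINITY_DN239_c0_g1_i7) was at 506 ± 211 FPKM and transferrin-like (TRINITY_DN1150_c0_g1_i4) at 271 ± 43.4. Heme metabolism held 0.034% ± 0.0091, including heme oxygenase 1 (TRINITY_DN1415_c0_g1_i1), which breaks down heme, at 30.9 ± 5.75 FPKM. The 122 unigenes of the detoxification lists held 0.425% ± 0.0228, led by cytochrome P450 6a9-like (TRINITY_DN1739_c0_g1_i2) at 420 ± 101 FPKM (SD, n = 3), and 0.643% of reads. The 83 immune unigenes held 0.304%, 0.308% and 0.660% in flies 1, 2 and 3. Within them, gram-negative bacteria-binding protein 3 (TRINITY_DN1937_c0_g1_i7), named for sensors of microbial glucans, was at 8.86, 61.0 and 573 FPKM, and argonaute 2 (TRINITY_DN2223_c0_g2_i11), which cuts viral RNA in RNA interference, at 351, 48.3 and 700 FPKM. The other 4 argonaute and piwi unigenes differed 1.45-fold to 3.69-fold between their highest and lowest fly, against 14.5-fold for argonaute 2.

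Markers of other tissues were present at unequal levels. Salivary names held 2.00% ± 0.415, mostly 3 unigenes of probable salivary secreted peptides at 3000 to 3092 FPKM on average. Muscle proteins held 0.213%, 0.205% and 0.448% in flies 1, 2 and 3. The fat body list held 0.0331%, 0.0377% and 0.121%, but 7 of its 16 members were apolipoprotein D names, lipocalins made in many tissues, and the 9 others held 0.00107%, 0.00383% and 0.0152%. Names of Malpighian tubule transporters and enzymes held 0.083% ± 0.0136, hemocyte names 0.0083% ± 0.0035, and stem and progenitor cell names 0.0165% ± 0.0108 (SD, n = 3). Of reads, Malpighian tubule names held 0.152% and hemocyte names 0.0156%, and without fly 3 stem and progenitor cell names held 0.0107% of FPKM. The enteroendocrine list matched 18 unigenes, but 16 of them only contained the letters of a saccharide name, and the 2 others held 0.0013%. Only 2 ovary and egg names were found, at 0.00023% on average and 5.91e-05% without fly 1, and no unigene matched the vertebrate blood list.

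The spread between individual flies was compared for lists of unigenes. Of 40 lists with a percentile, 17 varied more than the matched random lists and 3 varied less. The 17 included cuticle proteins (median SD 2.09), fat body (1.67), chymotrypsin, other serine proteases (1.29), melanization (1.20), protease inhibitors (1.17), neuron and sensory proteins (1.13), stem and progenitor cells (0.82) and immune recognition (0.76). Without fly 3, 9 lists varied more. Proteasome and ubiquitin, visceral muscle and amino acid transporters were no longer among the lists that varied more after median-of-ratios scaling, at percentiles of 14.7, 61.4 and 75.5, and neither were lipases, at 96.6. With that scaling 7 other lists varied more than the random lists, trypsin (percentile 99.23), aminopeptidases and dipeptidases (99.75), amylases and glucosidases (98.94), cytochrome P450 enzymes (99.99), UDP-glycosyltransferases (99.75), ABC transporters (98.68) and Malpighian tubule names (99.55), for 20 in all.

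**Figure D3:**
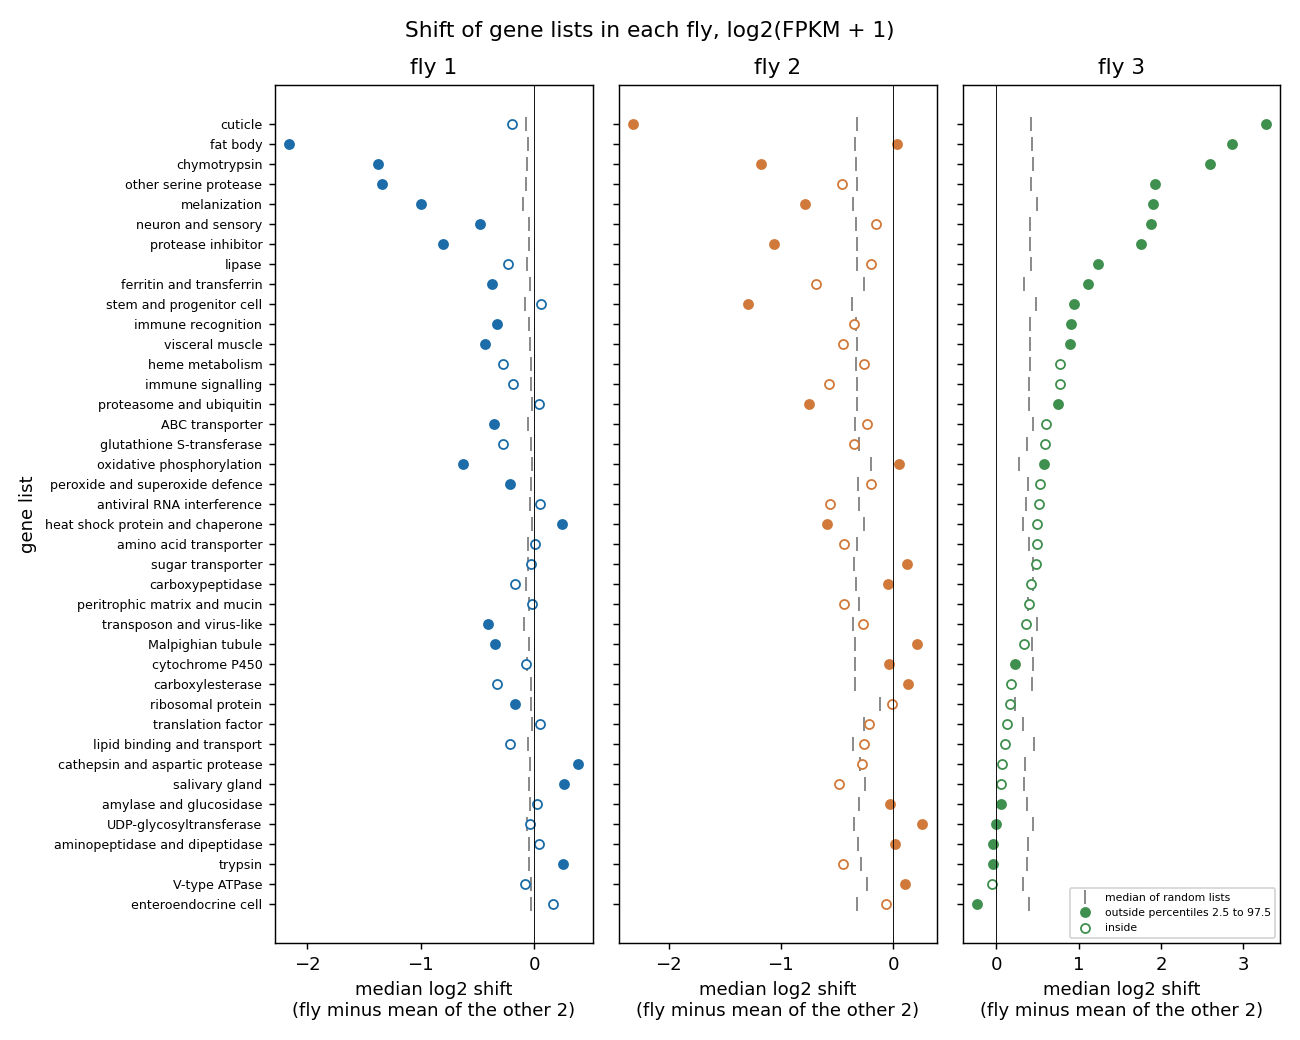
Median log2 shift of each gene list in each fly against the mean of the other 2, with filled points beyond all but 2.5% of matched random lists at either end and grey ticks at the median of those lists. In fly 3, cuticle lies at 3.28, fat body at 2.86, or 1.76 without lipocalin names, and chymotrypsin at 2.60, and 14 lists lie above the random lists.

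Fly 3 stood apart from the other flies in the largest number of unigenes. The median shift of all 7384 unigenes with a mean FPKM of at least 1 was -0.05 in fly 1, -0.33 in fly 2 and 0.42 in fly 3, so list shifts are given relative to random lists. In fly 3, 14 lists lay above the random lists and 6 below. The 6 include the enteroendocrine list, of whose 18 members 16 were false name matches. Without such matches it had too few members for a percentile, and salivary names lay below, at 1.73. Of the other serine proteases with a mean FPKM of at least 1, 55 of 66 were higher in fly 3 than in the mean of the other flies, with a median shift of 1.93, although the dominant members were lowest there. The 11 melanization unigenes at that level, of the pathway that seals wounds and microbes in pigment, were also higher in fly 3 (median shift 1.91), as were 41 of 46 immune recognition unigenes (0.91) and 13 of 14 protease inhibitors (1.76). With median-of-ratios scaling these 4 lists still lay above the random lists, with 50 of 62 other serine proteases (1.59), 9 of 11 melanization unigenes, 28 of 45 immune recognition unigenes (0.42) and 10 of 14 protease inhibitors (1.32) higher in fly 3. A high value in fly 3 helps a unigene reach that mean, and with no filter the unscaled counts were 69 of 81 (median shift 1.70), 11 of 13 (0.98), 42 of 49 (0.73) and 17 of 18 (1.00), in the same order, still above the random lists. Lists of other tissues and functions also lay above the random lists with no filter. Among them were visceral muscle (27 of 30 higher, 0.89), fat body with lipocalin names (13 of 16, 1.76) and oxidative phosphorylation (41 of 41, 0.58). Amylases and glucosidases (0.05), cytochrome P450 enzymes (0.23) and aminopeptidases and dipeptidases (-0.04) lay below the random lists in fly 3, and with median-of-ratios scaling their shifts were -0.43, -0.28 and -0.46. With no filter these 3 lists no longer lay outside the random lists, at percentiles of 2.78, 6.54 and 13. Trypsins (percentile 1.74), UDP-glycosyltransferases (0.23) and the enteroendocrine list (0.03) also lay below the random lists in fly 3. With no filter they stayed below, at 1.69, 0.22 and 0.37. With median-of-ratios scaling they were at 3.775, 0.41 and 0.03, so trypsins no longer lay outside. In fly 2, stem and progenitor cell unigenes (-1.29, 0 of 16 members higher), proteasome and ubiquitin (-0.75) and heat shock proteins and chaperones (-0.58) lay below the random lists. In fly 1, oxidative phosphorylation lay below them (-0.62, 0 of 41 members higher) and heat shock proteins and chaperones above (0.24).

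Of 5256 unigenes with a mean FPKM of at least 5, 495 (9.42%) were variable. The highest value lay in fly 3 for 435 of them, in fly 1 for 39 and in fly 2 for 21. After median-of-ratios scaling, 395 were variable, with 281 highest in fly 3, 45 in fly 1 and 69 in fly 2, a share of 71.1% in fly 3 against 87.9% without scaling. Without fly 3, 149 unigenes were variable, and without fly 2, 299. Omega-amidase NIT2 (TRINITY_DN8655_c0_g1_i2), named for an enzyme of nitrogen metabolism, was at 5.23, 544 and 3596 FPKM in flies 1, 2 and 3. Odorant binding protein 4 (TRINITY_DN1320_c0_g1_i2), from a family of small carriers of hydrophobic molecules, was at 9.22, 152 and 2150 FPKM, and general odorant-binding protein 56h (TRINITY_DN7083_c0_g1_i2) at 1.11, 12.4 and 592. Uricase (TRINITY_DN8991_c0_g1_i5), which degrades uric acid, was at 0.045, 23.2 and 146 FPKM. A unigene of ERI1 exoribonuclease 2-like (TRINITY_DN8042_c0_g1_i4) was lowest in fly 2, at 45.4, 0.761 and 411 FPKM. Of the 20 most variable unigenes, those without a protein hit are not named. Each fly has 1 library, so these differences have no replicate check within a fly.

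**Figure D4:**
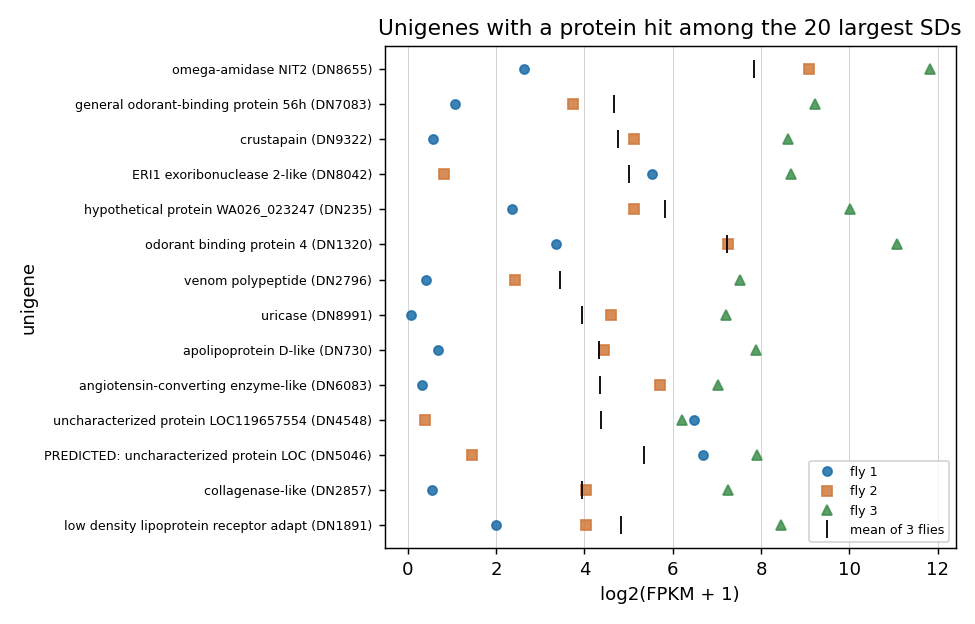
log2(FPKM + 1) of the unigenes with a protein hit among the 20 with the largest between-fly SD, 1 symbol per fly and a vertical tick at the mean of 3 flies. Omega-amidase NIT2 has an SD of 4.71 and odorant binding protein 4 an SD of 3.86 on this scale.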

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

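The values here were singled out after the data were seen, because they come from unigenes that belong to no gene list, although these entered the counts over all unigenes. A unigene of 12558 bases whose best hit is a Nora-like virus (TRINITY_DN613_c0_g1_i5, 88.2% identity) was at 19.6 FPKM in fly 1 and 35.5 FPKM in fly 3, from 7854 and 13068 reads. Fly 2 had 0 reads of it, which allows up to 0.0141 FPKM at 3 fragments, or 6 reads, so the unigene was at least 1386-fold higher in fly 1 and at least 2512-fold higher in fly 3. The 141 unigenes without a protein hit held 1.43%, 1.16% and 1.89% of all FPKM in flies 1, 2 and 3, a mean of 1.49% ± 0.371 (SD, n = 3), led by TRINITY_DN373_c0_g2_i6 at 4142 ± 406 FPKM.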

How the results depend on the processing

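Lists without false name matches, without bacterial best hits or with no filter on low values, names from the first title only and shares of reads were chosen after seeing the data, and the other alternatives before. Counts of detected unigenes, the shares of the 10 and 100 most abundant unigenes and the mean FPKM of all 166 named unigenes stayed within 1.5 times or 1 SD under every alternative run, although leaving out 1 of 3 flies cannot move a mean by 1 SD. The mean correlation between flies, 0.91 ± 0.02, was 0.88 with a pseudocount of 0.1 and 0.85 with 0.01, and 0.89 to 0.94 with 1 fly left out. Without the 10 most abundant unigenes, ribosomal proteins held 23.5%, serine proteases 3.97% and digestive lists 7.93%, since the denominator and the leading members changed. Without bacterial best hits, serine proteases held 1.88% and digestive lists 4.55%. As a share of reads, which weights unigenes by length, ribosomal proteins held 10.4%. With the median of members, the log2 ratios of serine proteases over exopeptidases (-1.54), digestive over immune lists (-0.045), cytochrome P450 over glutathione S-transferase (-2.24) and ferritins and transferrins over peroxide and superoxide defence (1.42) reversed, and the cause was not tested. Variable unigenes numbered 750 at a mean FPKM of at least 1, which tests more unigenes, and 149 to 416 with 1 fly left out. Leaving out a fly cannot widen the range of a unigene, so a lower count is partly built in. Those highest in fly 3 fell from 435 to 281 with median-of-ratios scaling. Lists that varied more than random numbered 9 to 15 with 1 fly left out, against 17. Lists that varied less numbered 1 with median-of-ratios scaling, against 3, and lists above random in fly 1 numbered 1 at a mean FPKM of at least 5, against 4. The cause of these changes in list counts was not tested. Visceral muscle varied more than random lists with 3 flies and less (percentile 0) without fly 3, with a range of 0 to 99.98 when 1 fly was left out. Melanization lay below random lists in fly 2 (percentile 1.18) and above them (99.1) with no filter on low values, which adds 2 low members. No paired analysis was possible because there is 1 group. The alternative with another protein database first was not run, since 1 best hit is listed. Depth limits the lowest unigenes, of which the smallest has 6 reads over 3 flies.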

Other observations

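The groups and tests in these paragraphs were chosen after the values were seen. Of all 8039 unigenes, 66.5% were highest in fly 3, and 41.1% after median-of-ratios scaling. The table held 44 unigenes named venom polypeptide after the robber fly Dolopus genitalis, with 0.682% ± 0.163 of all FPKM (SD, n = 3). Of these, 34 were highest in fly 3, and 27 after scaling, although their summed FPKM was lowest there, at 5460, 3879 and 3638 in flies 1, 2 and 3. TRINITY_DN334_c0_g1_i5 was at 1449, 1142 and 134 FPKM in flies 1, 2 and 3, and TRINITY_DN2796_c0_g1_i1 at 0.331, 4.38 and 182. The 14 odorant-binding proteins held 0.00582%, 0.0306% and 0.453%, and 11 of them were highest in fly 3 with or without scaling. Of 62 unigenes named as clip-type serine proteases, glucan-binding proteins, spaetzle or phenoloxidase proteins, which belong to the immune cascade of the insect blood, 57 were highest in fly 3, and 53 after scaling, and their sum was at 79.5, 206 and 1469 FPKM. Heat shock protein 70-S1 (TRINITY_DN688_c0_g1_i3) was at 524, 18.3 and 180 FPKM.

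The most abundant protease transcripts carry bacterial species names. The 12 unigenes with a best hit in Bacteroides fragilis or Phocaeicola vulgatus held 22.6%, 33.0% and 7.22% of all FPKM in flies 1, 2 and 3. RNA of these 2 bacteria in the gut is argued against by the identity to their own proteins, with a median of 76.2%, an upper quartile of 85.0% and 11 of 12 unigenes under 95%, although RNA of a related bacterium is not excluded by this. Fly sequence filed under a bacterial name is a candidate explanation that stays open. Only 1 bacterial ribosomal protein name occurred under these species, and 0 of the 12 unigenes listed a record of another species, so it cannot be told apart from RNA of a related bacterium without the sequences.

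Fly 3 has the highest value of most variable unigenes. If the smaller share of the dominant proteases in fly 3 had set this through normalisation, scaling would remove it, but 71.1% of variable unigenes (281 of 395) were still highest in fly 3 after median-of-ratios scaling, with a median log2 shift of 2.46 and a lower quartile of 1.88. A lower share of gut epithelium would raise all other tissues alike. The 26 muscle markers had a median shift of 0.53 and an upper quartile of 0.69, with 21 of them at a mean FPKM of at least 5. That upper quartile lies under the lower quartile of 1.88 of the variable unigenes highest in fly 3. Those unigenes were selected for a large difference, so the comparison cannot argue against this explanation. Of the muscle markers, 24 of 26 were higher in fly 3, at percentile 99.97 of matched random lists. With the same scaling, cuticle (median shift 3.03), neuron and sensory (1.48) and stem and progenitor cell (0.67) lists also lay above random lists. Malpighian tubule names (-0.24, 9 of 25 higher, percentile 4.24) and salivary names (-0.28, 6 of 18, percentile 15.8) did not. These lists were thus not raised alike. Whether their names mark the tissue here was not tested, and a lower share of epithelium stays open as an explanation. Fat body tissue carried over with the gut of fly 3 cannot be told apart from other causes, since the 9 fat body names other than lipocalins, with no filter on their values, had a median shift of 1.29, at percentile 99.99 of matched random lists but with an upper quartile of 1.48, and 2 of 9 had a mean FPKM of at least 5, apolipophorins (TRINITY_DN9332_c0_g1_i15) at 64.1 and vitellogenin-1-like (TRINITY_DN4151_c0_g1_i6) at 12.4 FPKM in fly 3. No biological explanation was tested, since the labels give no difference between the flies.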
